A study of Mus musculus with 16 samples.

How the data were processed

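Astrocytes were sorted from the thalamus and the spinal cord of 4 mice at postnatal day 15, and each region gave an IL-33 reporter-positive and an IL-33 reporter-negative library per mouse. This made 16 libraries in 4 groups of 4. The mice carried 1 copy of an mCherry reporter of Il33 and a GFP reporter of Aldh1l1, a gene used as an astrocyte marker, per the labels. Replicates of a group came from separate mice, and the mouse number was the same for the 4 libraries of an animal.

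Total RNA was isolated from the sorted cells with a Qiagen micro kit, and the libraries were made with a NuGEN kit, per the labels' protocols. How the GFP reporter entered the sort is not given in the sources used here. The submitters' processing notes name FastQC, TopHat2 2.0.11, Bowtie2 2.2.3, HTSeq 0.6.1p1, Cuffnorm, Cufflinks, DESeq2 and the genome build GRCm38. The table used here holds FPKM values, fragments scaled by transcript length and library size, that the authors deposited for 39171 features in the 16 libraries. The median-of-ratios factors of these values ran only from 0.951 to 1.08, while mitochondrial transcripts took 43.7% to 73.9% of the summed FPKM. The values may thus already have been normalized between libraries. In that case the median-of-ratios rescaling used below largely repeats that step. A deposited comparison table of positive against negative libraries holds the authors' group means in FPKM, a log2 fold change with its standard error, a test score and a p-value with its adjusted form. Its group means equalled the means of the deposited FPKM values within a relative error of 2.2e-16.

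The file gave no symbol for 16252 features; 15208 of these were named from the reference table by identifier and 1044 had no name. Coordinates are those of the GENCODE vM21 annotation of GRCm38. No pair of libraries was identical (0 pairs), and 10611 features were at 0 in every library. Sequencing depth is unknown, because the low FPKM values did not fall on whole-read steps, so no counting interval is given. Some very abundant transcripts were listed at exactly 0 in some libraries, which can be a failed estimate. In 410 features a library was at 0 while another library of its group was at 100 FPKM or more; 11 of these were protein-coding and 360 were short RNAs. Such features are reported as listed at 0, with no fold.

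Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with one coefficient per group over all 16 libraries and a trended prior. The 16340 features with at least 1 FPKM in at least 4 libraries were tested. A fold change on this scale understates the change of weakly expressed genes. Calls have a Benjamini-Hochberg adjusted p under 0.05. There were 6 comparisons: positive against negative in each region, their mean, their difference, and spinal cord against thalamus in each gate. Il33 and Aldh1l1 were also tested with a two-sided exact permutation test of the difference of mean FPKM. Gene lists, 43 in all and 42 with at least 3 tested members, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The design, gene lists and most alternatives were fixed before the data were examined.

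Named genes were chosen by a rule. Il33 and Aldh1l1 were always named. In each positive against negative comparison the 8 genes with the largest changes in each direction were taken among those called, with a mean of at least 2 FPKM in the higher group and the same direction in all 4 mice. For the mean of both regions a gene had to be called in both. The regional comparisons took 6 by the same criteria and the difference took 5 called genes in each direction. Up to 4 members were added for a list past the threshold and up to 2 for other lists. Clone names, predicted genes and pseudogenes were not named. List members that missed the threshold were left out of the text and of the tested alternatives, a restriction made after their values were seen. The genes whose group means are printed were set by a further rule made after the values were seen: the first 3 in each direction of each positive against negative comparison, the first 2 of the others, and the 2 most abundant members of 4 cell type lists. Some items that these rules take are not reported here.

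The mouse numbers pair the libraries because those of one number came from the same animal, per the labels. Sex-linked transcripts were checked against the numbers: Xist lay at 175 to 468 FPKM in the 4 libraries of mouse 1 and at most 1.46 FPKM in those of the other mice. Ddx3y lay at most at 0.0976 FPKM in mouse 1 and at 6.65 to 11.9 FPKM in the others. By these transcripts mouse 1 was the only female, so the check cannot tell mice 2, 3 and 4 apart. Results without mouse 1 are also results without the only female. Deviations from the group means had a mean correlation of 0.036 across the 24 same-mouse pairs, from -0.014 to 0.092, and of -0.012 across the 72 other pairs. The fit with the mouse as a block was an alternative. The others were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios rescaling, only the groups compared, and leaving out each library and each mouse. Library weights and protein-coding genes not listed at 0 were added after seeing the data.

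The fit was tested on simulated data, with 200 genes changed in each of 5 simulations of 16340 features per comparison. With one spread for all groups, genes that had not been changed made up 4.46% to 6.6% of the calls. With the measured spread of each group they made up 32.4% in the thalamus comparison of gates and 20.7% in the spinal cord. Between regions they made up 58.6% in negative libraries and 6.36% in positive libraries. In that order these were on average 63, 32.6, 195.4 and 8.4 features per simulation. The shares depend on how many genes were changed, so they are not shares of the calls in the real data. The shared estimate of the spread is therefore not met by these libraries, whose median SD on the log2 scale was 0.54 and 0.47 in the negative and 0.22 and 0.19 in the positive groups of thalamus and spinal cord. The design had been fixed, so this fit stayed the main one. Counts from only the groups compared are given beside the comparisons of gates within a region and of regions within a gate. Changes of 4-fold were recovered in 83.4%, 82%, 84.8% and 82.6% of genes in the same order of comparisons, and changes of 2-fold in 41.2%, 37.2%, 46% and 36.2%. The changed genes were drawn from features above a minimum mean, so these rates do not cover weakly expressed genes. The changed list was called in 5 of 5 simulations of each comparison, but genes were drawn independently and its members were changed alike. Neither this nor the shares above cover the correlation between genes in the real data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.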

Results

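RNA was measured in astrocytes sorted by an Il33 reporter from the thalamus and the spinal cord of 4 mice, with 4 libraries in each of 4 groups. The summed FPKM of a library ran from 984986 to 2344480, and 13260 to 14731 features reached 1 FPKM. Mitochondrial transcripts took 43.7% to 73.9% of the summed FPKM, with 62.7 ± 7.91% in negative and 54.9 ± 2.49% in positive thalamus libraries and 57.1 ± 11.0% and 46.2 ± 2.25% in those of the spinal cord (SD, n = 4). Features at 1 FPKM or more numbered 13771 ± 364 and 14577 ± 157 in the thalamus and 13661 ± 311 and 14151 ± 94.9 in the spinal cord, in the same order. The mean Pearson correlation across features of a library with the others of its group was 0.784 in negative and 0.879 in positive thalamus libraries and 0.806 and 0.900 in the spinal cord. These differences between the gates were not tested, and the shares and sums cannot be compared between the gates, because abundant mitochondrial transcripts were listed at 0 in some libraries, mt-Co1 in every negative and 1 of the positive ones. Depth is unknown for these values. The first principal component held 28.4% of the variance and the second 11.7%.

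The first question was whether the Il33 transcript, which encodes an alarmin cytokine, followed the reporter. In the thalamus Il33 (chromosome 19, 29925114 to 29960718) was at 27.4 ± 3.41 FPKM in positive and 18.6 ± 6.01 FPKM in negative libraries (SD, n = 4), and it was higher in the positive library of 4 of 4 mice. In the spinal cord it was at 27.9 ± 3.49 FPKM and 24.6 ± 7.93 FPKM (SD, n = 4), and higher in 3 of 4 mice. Neither difference passed the test, with p = 0.0857 in the thalamus and p = 0.571 in the spinal cord (two-sided exact permutation test, smallest possible p 0.0286). The log2 fold change was 0.58 ± 0.22 (SE) in the thalamus, with a limma adjusted p of 0.0736 (0.0111 to 0.318 over 20 other settings, under 0.05 in 4), and 0.21 ± 0.22 in the spinal cord, with an adjusted p of 0.559. Without the thalamus negative library of mouse 1 the thalamus difference was 11.6 FPKM, with an exact permutation p of 0.0286. Without the spinal cord negative library of mouse 1 the spinal cord difference was 7.21 FPKM, against 3.26 FPKM with it, with an exact permutation p of 0.0571. Leaving out any other library of the region gave 7.07 to 10.0 FPKM in the thalamus and 1.71 to 4.35 FPKM in the spinal cord. The exact permutation p was then at least 0.0857 and 0.457.

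Aldh1l1, the folate enzyme gene that the GFP reporter of these mice follows, was at 18.3 ± 0.607 FPKM in positive and 24.98 ± 11.6 FPKM in negative thalamus libraries (SD, n = 4). In the spinal cord it was at 25.4 ± 1.12 FPKM and 19.9 ± 2.78 FPKM (SD, n = 4). The limma adjusted p was 0.375 in the thalamus and 0.36 in the spinal cord, while the exact permutation p was 0.429 and 0.0286. With the libraries paired by mouse, the exact permutation p in the spinal cord was the smallest that 4 pairs allow, which is above the threshold. The plot of Il33 and Aldh1l1 per library shows the value of each library.

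**Figure D1:**
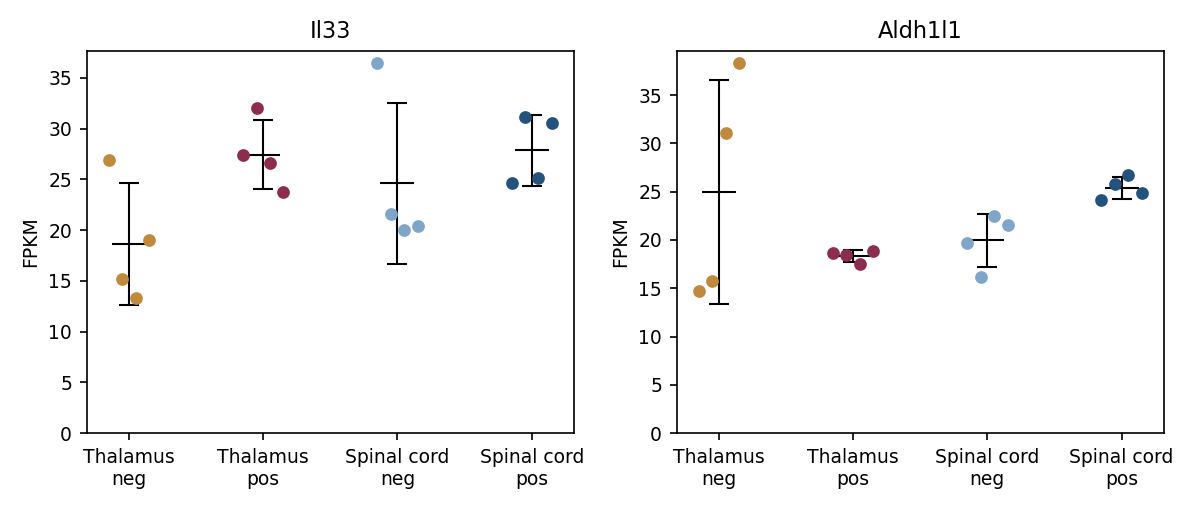
FPKM of Il33 and Aldh1l1 in each of the 16 libraries, with group means and SD as bars (n = 4). Il33 in the spinal cord negative library of mouse 1 sits at 36.5 FPKM, above the positive libraries of that region, which reach 31.2 FPKM.

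In the thalamus, the question was what distinguishes reporter-positive from reporter-negative astrocytes. Among the named genes with the largest decreases in positive libraries were several genes of cilia. Enkur, a sperm and cilium protein gene, was at 74.5 ± 32.2 FPKM in negative and 0.813 ± 0.613 FPKM in positive libraries (SD, n = 4). Ak7, an adenylate kinase gene of cilia, was at 42.8 ± 9.27 FPKM and 0.167 ± 0.167 FPKM. The amino acid transporter gene Slc38a1 was at 58.4 ± 10.3 FPKM and 0.491 ± 0.143 FPKM. Rsph1, Dynlrb2, Tmem212 and Ccdc146 fell by 5.18, 5.18, 5.12 and 4.99 on the log2 scale.

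All 15 ependymal markers tested were lower in positive thalamus libraries, with a median log2 fold change of -3.68 (camera adjusted p = 1.2e-21), and all 15 were called when adjusted over the list alone. The oligodendrocyte list had 15 of 18 members lower and 0 higher, with a median of -2.54 (camera adjusted p = 2.6e-14) and 15 adjusted over the list alone. Mbp, the gene of a major myelin protein, was at 224 ± 70 FPKM in negative and 29.9 ± 4.21 FPKM in positive libraries (SD, n = 4). Of 12 oligodendrocyte precursor markers, 8 were lower, with 8 adjusted over the list alone, among them Sox10 (-3.33 ± 0.22, SE) and Gpr17 (-3.36 ± 0.23). These lists held with an estimated correlation, at adjusted p = 0.0019, 0.025 and 0.0019.

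Genes of fibrous, white matter astrocytes were also lower in positive thalamus libraries, 12 of 16 with 0 higher and a median of -1.42 (camera adjusted p = 3.4e-08; adjusted p = 0.02 with an estimated correlation; 12 adjusted over the list alone). Among them were the intermediate filament genes Vim (-4.16 ± 0.27) and Gfap (-3.44 ± 0.33), and Igfbp5 (-3.13 ± 0.30). Markers of oligodendrocytes and ependymal cells moved in the same direction in the same libraries. Of 25 neurotransmitter receptor genes of astrocytes, 7 were higher and 2 lower (10 and 2 adjusted over the list alone), led by the glutamate receptor gene Gria2 (2.04 ± 0.22). That list had a camera adjusted p of 0.0421, which rose to 0.0507 with the mouse as a block, 0.0715 with only the groups compared and 0.17 with an estimated correlation. It was 0.0884 without the positive and 0.123 without the negative thalamus library of mice 1 and 2 in that order, and 0.00678 to 0.138 over all other settings. Protoplasmic astrocyte genes were higher in 7 of 17 members and lower in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0909), and pan-astrocyte markers in 3 and 4 of 20 (4 and 4 adjusted over the list alone; camera adjusted p = 0.617). Neuron markers were lower in 6 of 13 members, with 9 adjusted over the list alone, such as Meg3 (-2.85 ± 0.27) and Snap25 (-2.22 ± 0.32), with an adjusted p of 0.019 with an estimated correlation. Microglia markers showed 1 of 12 members lower, also adjusted over the list alone, and a median of -0.14 (camera adjusted p = 0.82).

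Among the named genes given a fold, the largest rises in positive thalamus libraries were those of Zfp691 (2.81 ± 0.56), Ccdc120 (2.52 ± 0.42), Nbeal2 (2.51 ± 0.70) and the noncoding Hotairm1 (2.19 ± 0.42). Nbeal2 lost its call without the positive thalamus library of mouse 1 (2.31, adjusted p = 0.0504) and without mouse 1, 2 or 4, with adjusted p = 0.116, 0.0839 and 0.0877 and a range of 0.00149 to 0.116 over all other settings. Cntf rose by 2.04 ± 0.31, but it overlaps Zfp91 and is uncertain. Several of the most abundant transcripts were listed at 0. Malat1 was listed at 0 in the 4 positive thalamus libraries and at 19126 to 46799 FPKM in the negative ones, and mt-Co1 was listed at 0 in the 4 negative libraries and at 22968 to 27854 FPKM in the positive ones.

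Of 16340 features, 4119 differed in the thalamus, 1890 higher and 2229 lower. After median-of-ratios rescaling 4349 differed, 2315 higher (53.2%, against 45.9% before) and 2034 lower. Among protein-coding genes 977 were higher and 2129 lower. Without mouse 3 the count was 2249 and without mouse 4 it was 2279. Fitted on only the groups compared it was 3042.

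In the spinal cord, the same question was asked of its reporter-positive and reporter-negative astrocytes. Among the named genes, those of the oligodendrocyte lineage were the most strongly lowered in positive libraries. Enpp6, a choline phosphodiesterase gene of newly forming oligodendrocytes, was at 250.3 ± 56.8 FPKM in negative and 1.25 ± 0.283 FPKM in positive libraries (SD, n = 4). Bmp4, a growth factor gene, was at 123 ± 37.6 FPKM and 0.678 ± 0.357 FPKM, and Cldn11, a tight junction gene of myelin, was at 150.3 ± 32.5 FPKM and 1.24 ± 0.531 FPKM. St18, Fa2h, Sox10, Bcas1 and Tubb4a fell by 6.02, 5.83, 5.74, 5.59 and 5.57 on the log2 scale.

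The oligodendrocyte list had 17 of 18 members lower in the spinal cord, with a median of -4.29 (camera adjusted p = 4.7e-27; adjusted p = 0.0046 with an estimated correlation; 17 adjusted over the list alone). Precursor markers were lower in 9 of 12 members, with 11 adjusted over the list alone. Mbp was at 950.0 ± 140 FPKM in negative and 67.3 ± 2.57 FPKM in positive libraries (SD, n = 4). Ependymal markers were lower in 13 of 15 members, with a median of -1.91 (adjusted p = 0.0088 with an estimated correlation; 13 adjusted over the list alone). Endothelial markers were lower in 9 of 15 members and higher in 1 (10 and 1 adjusted over the list alone), led by Flt1 (-2.59 ± 0.21), with an adjusted p of 0.0045 with an estimated correlation. Microglia markers were lower in 2 of 12 members, 1 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.36). The plot of marker levels shows these lists per library.

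**Figure D2:**
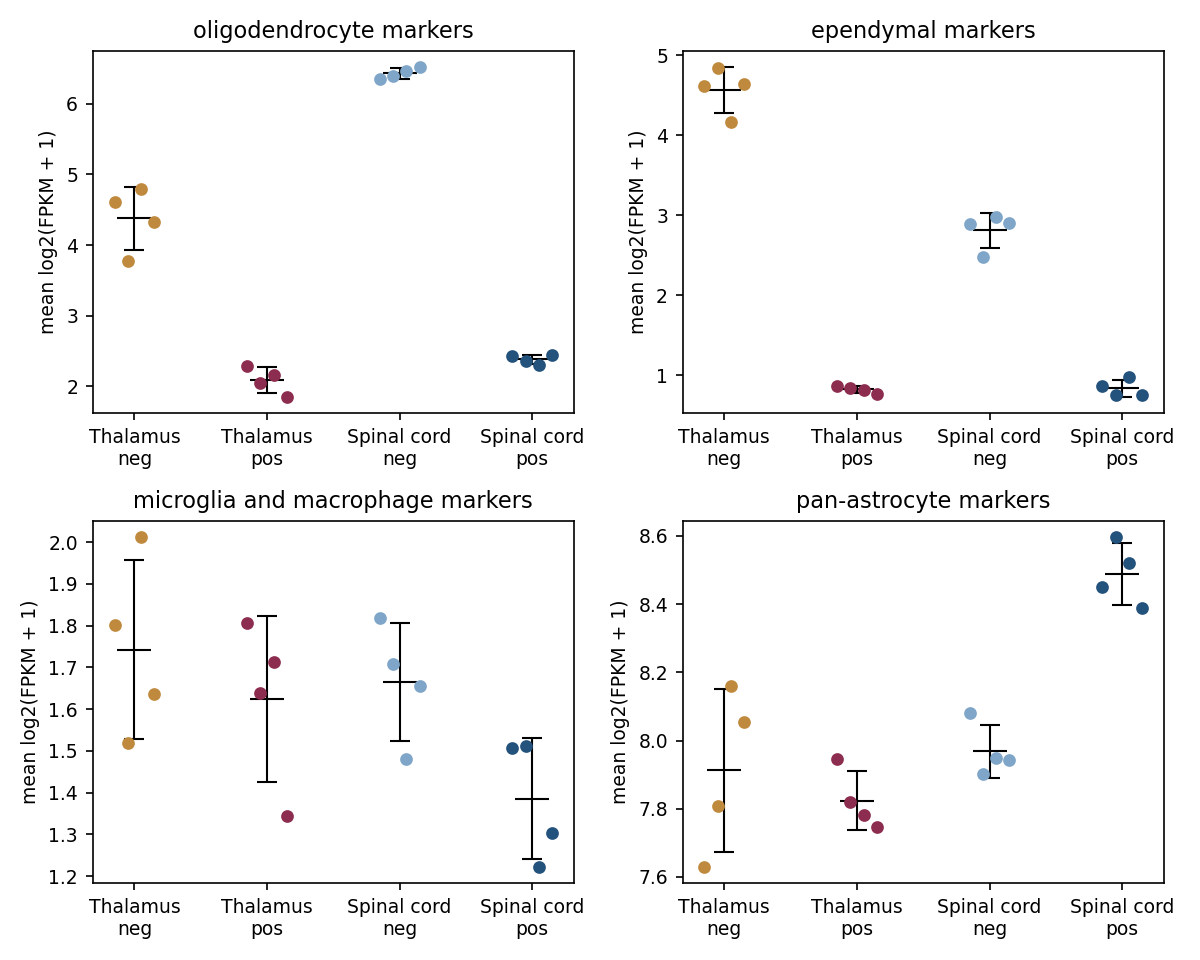
Mean log2(FPKM + 1) over the members of 4 marker lists in each library, with group means and SD as bars (n = 4); each panel has its own vertical range. Oligodendrocyte and ependymal markers lie lower in the positive libraries of both regions.

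Genes of protoplasmic, grey matter astrocytes were higher in positive spinal cord libraries in 11 of 17 members, with 0 lower and a median of 0.85 (camera adjusted p = 1.1e-07; adjusted p = 0.045 with an estimated correlation; 13 adjusted over the list alone). Htra1, a secreted protease gene, rose by 2.22 ± 0.26, the connexin gene Gjb6 by 1.63 ± 0.19, the amino acid transporter gene Slc7a10 by 1.55 ± 0.18 and Fgfr3 by 1.61 ± 0.20. Neurotransmitter receptor genes were higher in 14 of 25 members and lower in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.026 with an estimated correlation), among them Adora2b (1.91 ± 0.26), Adra2a (1.32 ± 0.21) and Grm3 (1.11 ± 0.17) higher and Gria3 (-2.01 ± 0.27) lower. Neurotransmitter transporters were higher in 5 of 13 members, with 7 adjusted over the list alone, but the list had an adjusted p of 0.082 with an estimated correlation. Fibrous astrocyte genes were lower in 9 of 16 members and higher in 1 (11 and 2 adjusted over the list alone), with Igfbp5 at -4.26 ± 0.30 and Vim at -3.54 ± 0.27 (camera adjusted p = 1.7e-04; adjusted p = 0.082 with an estimated correlation). Oligodendrocyte markers moved in the same direction as the fibrous genes in these libraries. Pan-astrocyte markers were higher in 8 of 20 members and lower in 1 (11 and 1 adjusted over the list alone), with adjusted p = 0.234 with an estimated correlation. The protoplasmic and pan-astrocyte lists share members, among them Gjb6 and Fgfr3. Whether the protoplasmic rise goes beyond a higher share of astrocyte RNA in positive libraries was not tested.

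The coagulation initiator gene F3 rose by 2.21 ± 0.21, the DNA methyltransferase gene Dnmt3b by 2.97 ± 0.46, the aminopeptidase gene Enpep by 2.47 ± 0.38, Il15ra by 2.11 ± 0.51 and Phf21b by 2.10 ± 0.53. Without mouse 1 or 2 Il15ra had adjusted p = 0.0939 and 0.0636 (0.00129 to 0.0939 over all other settings), and without mouse 2 or 4 Phf21b had 0.0666 and 0.0545 (0.00382 to 0.0666). Enpep was at 23.1 ± 6.15 FPKM in positive and 4.10 ± 3.70 FPKM in negative spinal cord libraries (SD, n = 4). Scarna8 was listed at 0 in the 4 negative spinal cord libraries and reached 14.8 FPKM in the positive ones. In total 3196 features differed, 1477 higher and 1719 lower, and among protein-coding genes 979 were higher and 1637 lower. Without mouse 3 the count was 1861 and without mouse 4 it was 2001. Fitted on only the groups compared it was 3423, above the 3042 of the thalamus, so the order of the regions depends on the fit.

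The regions were then set side by side. Higher in positive libraries of both regions were 690 features, against 170.8 for independent lists, and lower in both were 1056, against 234.5. The fold changes of the regions had r = 0.64 across genes, which are not independent replicates. In the mean of both regions Pfkp, a phosphofructokinase gene of glycolysis, rose by 1.97 ± 0.17, the hypoxia-related transcription factor gene Hif3a by 1.92 ± 0.24, F3 by 1.88 ± 0.15, Htra1 by 1.78 ± 0.18 and Il18 by 1.75 ± 0.21. Pfkp was at 199 ± 32.2 FPKM in positive and 48.1 ± 15.8 FPKM in negative spinal cord libraries (SD, n = 4), and at 90.5 ± 11.4 and 24.7 ± 8.21 FPKM in the thalamus. Enpp6, Bmp4, Enkur, Cfap54 and Cldn11 fell by 5.58, 4.97, 4.78, 4.77 and 4.69. The mean comparison called 6306 features, 3225 higher and 3081 lower, and among protein-coding genes 1849 were higher and 2926 lower.

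**Figure D3:**
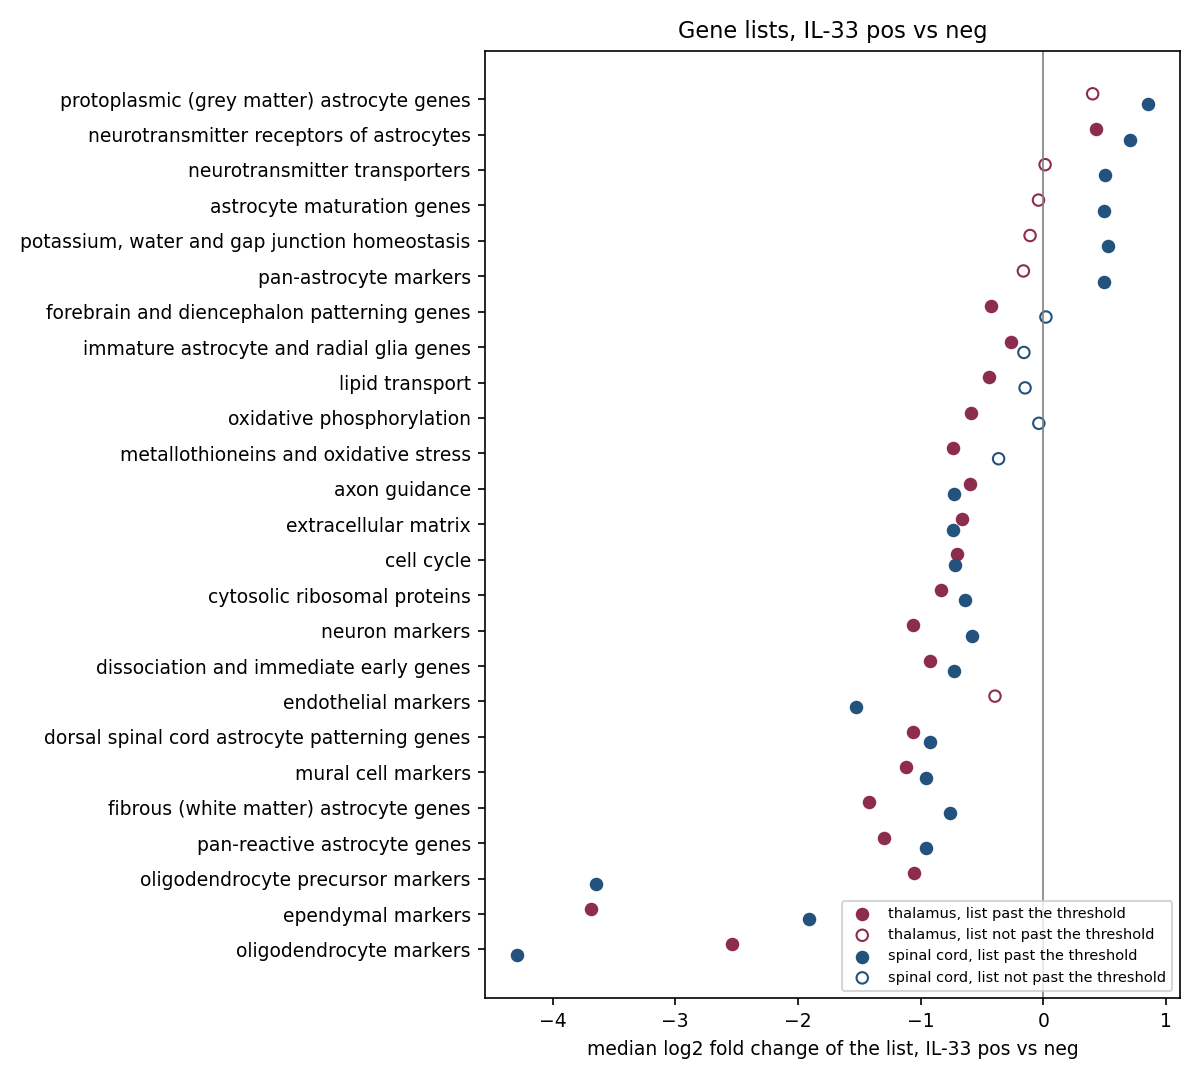
Median log2 fold change of each gene list in positive against negative libraries, for lists past the threshold in at least 1 region; filled points are past the camera threshold in that region and open points are not. Ependymal markers have medians of -3.68 in thalamus and -1.91 in spinal cord, and oligodendrocyte markers -2.54 and -4.29.

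Whether the gate difference itself differed between regions was tested directly, and 418 features passed, 184 with a higher value in the spinal cord and 234 with a lower one. Oligodendrocyte markers had the more negative effect in the spinal cord, in 10 of 18 members and a median of -1.78 (adjusted p = 0.02 with an estimated correlation; 15 adjusted over the list alone), with Ermn at -2.21 ± 0.28 and Ugt8a at -2.48 ± 0.37. Precursor markers followed in 6 of 12 members, with 8 adjusted over the list alone, among them Sox10 at -2.40 ± 0.31. Some of these genes were about equally low in positive libraries of both regions. Cldn11 was at 1.24 and 1.31 FPKM in those of spinal cord and thalamus, and at 150.3 and 23.4 FPKM in the negative ones. For such genes the difference restates the regional difference of negative libraries. Ependymal markers had the more negative effect in the thalamus, in 8 of 15 members and a median of 1.79 (adjusted p = 0.011 with an estimated correlation; 10 adjusted over the list alone), with Hydin at 1.79 ± 0.22 and Tmem212 at 3.99 ± 0.38, whose adjusted p was 0.0594 with a pseudocount of 0.1 (1.8e-05 to 0.0594 over all other settings). Among the 10 genes taken by size, Cdhr4 lost its call with that pseudocount (adjusted p = 0.0975) and without mouse 4 (0.0515; 5.5e-04 to 0.0975 over all other settings), and Dusp15 without mouse 2 (0.0616; 1.3e-04 to 0.0616). The collagen gene Col14a1 was at 24.97 ± 2.72 FPKM in spinal cord negative libraries and 0.171 ± 0.0478 FPKM in positive ones (SD, n = 4), and at 0.0422 ± 0.0526 and 0.260 ± 0.170 FPKM in those of the thalamus. Of the 418 features, 139 had means under 2 FPKM in both gates of a region, where a fall can hardly be measured. The count was 271 with a filter at 5 FPKM, 129 without mouse 3 and 659 without the thalamus negative library of mouse 1. It was 134 without mouse 2, 135 without mouse 4, and 254, 244 and 258 without the positive spinal cord libraries of mice 1, 2 and 3. It was 250 and 268 without the positive thalamus libraries of mice 3 and 4.

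Spinal cord and thalamus were compared within each gate to ask how astrocytes of the regions differ. Hox genes, which set position along the body axis, were higher in the spinal cord in 23 of 25 members in negative and 24 of 25 in positive libraries. Their camera adjusted p was 4.4e-36 and 2.8e-46, and 24 were called in each gate when adjusted over the list alone. Hoxc8 was at 47.8 ± 7.79 FPKM in spinal cord negative and 40.1 ± 5.79 FPKM in spinal cord positive libraries, against 0.241 ± 0.0898 and 0.367 ± 0.0982 FPKM in the thalamus (SD, n = 4). Forebrain patterning genes were lower in the spinal cord in 9 of 15 and 6 of 15 members (10 lower with 1 higher, and 6 lower, adjusted over the list alone). Otx2, a homeobox gene of the anterior brain that is also a choroid plexus marker, was at 43.4 ± 6.61 and 35.3 ± 4.11 FPKM in thalamus negative and positive libraries, against 0.0671 ± 0.0317 and 0.117 ± 0.107 FPKM in the spinal cord (SD, n = 4). Both lists held with an estimated correlation in both gates.

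**Figure D4:**
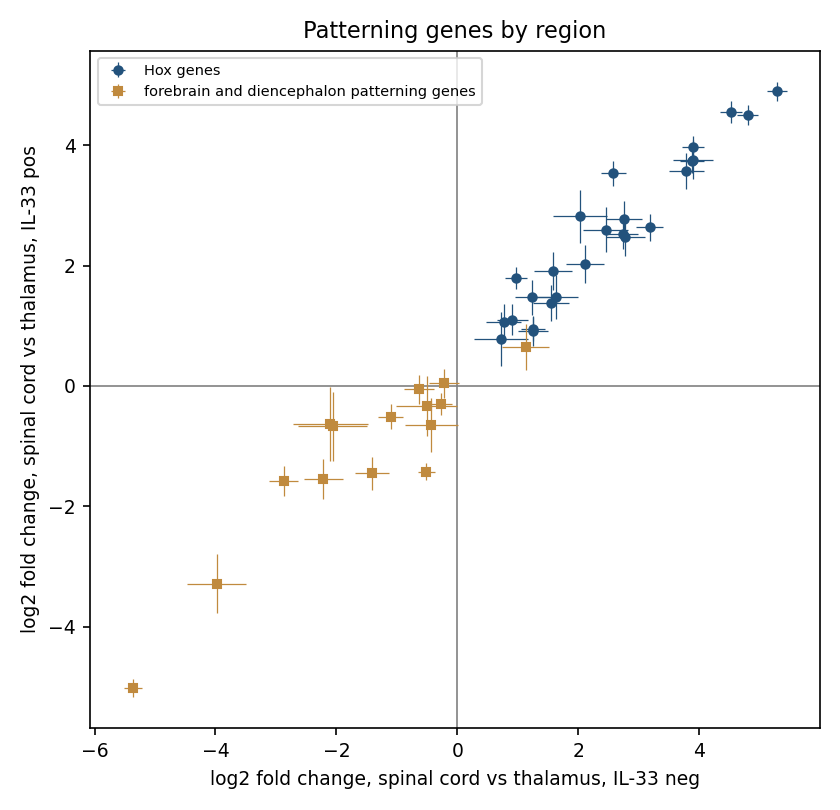
Log2 fold change, spinal cord against thalamus, of Hox and forebrain patterning genes in negative libraries (horizontal) and positive libraries (vertical), with standard errors as bars. Hoxc8 lies at 5.29 and 4.90, and Otx2 at -5.37 and -5.02.

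In negative libraries the spinal cord also held more of 16 of 18 oligodendrocyte markers, such as Mbp (2.13 ± 0.20), and less of 10 of 15 ependymal markers, such as Tmem212 (-4.30 ± 0.27), with adjusted p = 0.0059 and 0.003 with an estimated correlation (16 and 14 adjusted over the list alone). The choroid plexus gene Ttr ran from 0.397 to 599 FPKM across the thalamus negative libraries, and its call (-5.11 ± 1.52) ended with only the groups compared (adjusted p = 0.273) and without either thalamus negative library of mice 1 and 2 (0.116 and 0.12). It also ended without any one of the 4 spinal cord negative libraries (0.0754 to 0.0854), with a range of 0.00228 to 0.344 over all other settings. Negative libraries differed between regions at 1603 features, 861 higher and 742 lower in the spinal cord. Fitted on only the groups compared the count was 353. It was 1037 without mouse 2 and 976 without mouse 4, and of the features left unchanged in data simulated with the measured spread of each group and fitted over all groups, 13% had p under 0.05.

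In positive libraries Enpep (4.42 ± 0.38), Lphn2 (4.26 ± 0.21) and the lipocalin gene Apod (4.08 ± 0.56) were higher in the spinal cord, and Nr2e1 (-3.99 ± 0.27), Sema5b (-3.73 ± 0.45), Scel (-3.63 ± 0.24), Gdf10 (-3.38 ± 0.35) and Six3 (-3.29 ± 0.49) were lower. Oxidative phosphorylation genes were higher in 14 of 24 members, such as Atp5b (1.29 ± 0.17), and glycolysis genes in 12 of 18, such as Ldhb (1.83 ± 0.16) and Aldoc (1.52 ± 0.21). With an estimated correlation these lists had adjusted p = 0.062 and 0.084, and 24 and 13 members were called when adjusted over the list alone. Positive libraries differed between regions at 996 features, 689 higher (69.2%) and 307 lower, and after median-of-ratios rescaling 58.5% of the calls were higher. Fitted on only the groups compared the count was 4227, 2258 higher (53.4%) and 1969 lower, and with library weights, chosen after seeing the data, 53.4% of 4940 calls were higher. In the corresponding simulation fitted over all groups 1.47% of the unchanged features had p under 0.05. The count was 611 without the spinal cord library of mouse 2, 649 and 644 without the thalamus libraries of mice 3 and 4, and 457, 368 and 432 without mice 2, 3 and 4.

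The authors' deposited table, as used here, holds 444 genes of positive against negative libraries, 223 higher and 221 lower, with adjusted p of at most 0.00976. All 444 were tested here, and 442 had the same sign in the mean of both regions, where 419 were also called with that sign at an adjusted p under 0.05 and 374 at one under 0.01, the threshold nearer to that of the table. At 0.01 the mean comparison here called 3849 features. These are the same libraries, so the comparison is not independent evidence. Of the 15 ependymal markers, 8 are in the authors' deposited table, and of the 18 oligodendrocyte markers, 0 are, while 15 and 17 were called here in the mean of both regions, both at 0.05 and at 0.01. Precursor, endothelial, neuron and mural markers also have 0 rows there, with 11, 11, 7 and 7 members called here at 0.05. Protoplasmic and fibrous astrocyte genes have 7 and 6 rows. Whether the table lists all the authors' calls is unknown here, so its count cannot be compared with the counts of calls here. Malat1 has a log2 fold change of 1.25 in the authors' deposited table and is listed at 0 in the positive libraries of the FPKM table. Il33 is in 0 of its rows.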

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

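All tests of explanations in this part, and the counts of other splits, were chosen only after the results were seen; for Il33 a first test with another bound on the number of genes was replaced, also after its result was seen.

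In the spinal cord negative library of mouse 1 Il33 was at 36.5 FPKM, far from the other 3 at 19.98 to 21.6 FPKM, and its summed FPKM was 2233800 against at most 1323800. The small difference of Il33 between the gates may come from reporter-positive cells in the negative libraries, which would keep every gene at or below the Il33 ratio of positive to negative libraries. In the spinal cord 59 protein-coding genes lay above that ratio plus 2 standard errors, both fitted over all groups and on only the groups compared (limma treat test). The other splits of 35 gave at most 0, but they mix the gates, which widens their spread, so this adds no support. With the ratio taken anew, 36 genes lay above the bound without the spinal cord negative library of mouse 1. Without any other library of that region or any mouse 15 to 73 did so. Such cells are therefore argued against there as the whole reason, though not as a part of it. In the thalamus 1 gene, Gria2, lay above the bound in both fits, which is too few to decide. Such cells cannot be told apart there from Il33 transcript in reporter-negative cells. A difference between the reporter protein and the transcript was not tested in either region. An exchange of the gates of mouse 1 in the spinal cord is argued against, because on 2653 genes called without that mouse its positive minus negative score was 1.247 (log2), with 1.501 to 1.59 in the other mice.

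Outlying libraries appeared in 14 of 139 groups of values, where chance gives about 1 in 20. In the thalamus negative library of mouse 3 Zfp691 was at 10.3 FPKM and Nbeal2 at 9.10 FPKM, above the other 3. Scarna8 was at 12.7 FPKM in the thalamus negative library of mouse 1 and at 29.4 FPKM in the thalamus positive library of mouse 4, and listed at 0 in the others of those groups. Enpep was at 0.166 FPKM in the thalamus positive library of mouse 3, Nppc at 0.0655 FPKM in that of mouse 4, and Tmem212 at 0.336 FPKM in the spinal cord positive library of mouse 2. Nr2e1 was at 61.7 FPKM in the thalamus negative library of mouse 2, against 20.7 to 23.1 FPKM in the others, and P2ry12 at 7.46 FPKM in that of mouse 1. Slc1a2 was at 2038 FPKM in the spinal cord negative library of mouse 4, the lowest of its group by a small amount. Rarres2 was lowest in the spinal cord negative library of mouse 2, at 2.44 FPKM, and in the spinal cord positive library of mouse 4, at 6.08 FPKM.

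The gate difference differed between regions at 418 features. The spinal cord effect minus the thalamus effect was 4.32 for Slc38a1, 3.99 for Tmem212, 3.78 for Emb, 3.67 for Cdhr4 and 3.49 for Ccna1. It was -4.73 for Col14a1, -3.63 for Nppc, -3.62 for Gdf10, -3.60 for Fndc1 and -3.37 for Dusp15. Tmem212, Emb, Cdhr4 and Ccna1 in the spinal cord and Col14a1, Nppc and Fndc1 in the thalamus had means under 2 FPKM in both gates, so their differences largely restate their near absence from a region. Its median was -1.78 for oligodendrocyte markers, -1.59 for precursor markers, -0.74 for endothelial markers and 1.79 for ependymal markers.

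Markers of some other cell types were higher in negative libraries, with oligodendrocyte genes leading in the spinal cord and ependymal genes in the thalamus. The microglia list did not pass the threshold in either region. A lower share of astrocytes that raises every other type alike is argued against, since the oligodendrocyte median lay 4.02 below that of microglia in the spinal cord (-4.02, 95% bootstrap interval -5.06 to -3.23). Cells of these types in the negative gate cannot be told apart from transcription of these genes in reporter-negative astrocytes. Over both regions 40 of 42 values of oligodendrocyte and ependymal list members at 10 FPKM or more in negative libraries were lower in positive ones, but this restates the pattern and decides nothing. Whether a gate on the Aldh1l1 GFP reporter removed such cells is unknown, because its use in the sort is not given in the sources used here. Mbp averaged 950.0 FPKM in spinal cord negative libraries.

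The counts of calls were set against those of other splits of the libraries, which ignore which libraries share a mouse. Those splits also mix the groups compared, so a difference between the groups widens their spread and lowers their counts. The real split gave the most calls each time, but chance is not excluded by this. In the thalamus 1 of 35 splits, the real one, gave 4119 calls and the highest other gave 8; in the spinal cord the values were 3196 and 4. Of 100 splits for the mean of both regions the real one gave 6306 and the highest other 380, and the 2 others that part all 8 mouse pairs gave at most 0. For the difference between regions, fitted on within-mouse differences, the real split gave 221 and the highest other of 35 gave 6. Between regions, positive libraries gave 996 against 9. Negative libraries gave 1603 against 534, and that other split set the libraries of mice 1 and 2 against those of mice 3 and 4. The same split by mouse gave 1 call in positive libraries. With the mouse as a block the count in negative libraries was 1541. Whether there is a structure by mouse was not tested further. Only 7 other splits of 35 part all mouse pairs as the real one does, too few for a share under 0.05, and their highest counts were 8, 2, 1, 94 and 4 for thalamus, spinal cord, the difference, negative and positive libraries.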

How the results depend on the processing

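Library weights and the restriction to protein-coding genes were chosen after seeing the data; the other settings were planned. Between regions, negative libraries gave 353 calls with only the groups compared and 762 with library weights, and positive libraries gave 4227 and 4940. Negative libraries vary more, and the fit over all groups shares one spread. The fit on only the groups compared also uses fewer libraries. In data simulated with one spread for all groups it recovered 17% of 2-fold changes between negative libraries, against 34.6% over all groups. The fall to 353 is thus not due to the spread alone. The difference between regions gave 271 calls at 5 FPKM, where fewer features were tested. Leaving out 1 library or mouse gave 2249 to 4855 calls in the thalamus, 1861 to 3006 in the spinal cord, 4268 to 6931 in their mean, 129 to 659 for their difference, 976 to 1808 between regions in negative and 368 to 838 in positive libraries. The Il33 difference ran from 7.07 to 11.6 FPKM in the thalamus and 1.71 to 7.21 FPKM in the spinal cord, and its exact permutation test passed the threshold only without the thalamus negative library of mouse 1. With the mouse as a replicate block the counts were 4107, 3205, 6297, 343, 1541 and 981 in the order above, and the paired exact permutation p of Il33 was the smallest that 4 pairs allow, which is above the threshold, in the thalamus and 0.625 in the spinal cord. Among gene lists and named genes the block ended the calls of 2 lists and 6 genes. Mouse 1 had the negative libraries with the highest mitochondrial share and was the only female by its sex-linked transcripts. Without mouse 1 the counts were 4070, 2653, 5707, 357, 1337 and 838.

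Il33 between regions in positive libraries was not called and reversed to -0.059 after rescaling, with -0.088 to 0.096 when a library or mouse was left out. Aldh1l1 was not called either, and in the mean of both regions it reversed to -0.092 with library weights, with -0.123 to 0.151 when a library or mouse was left out; between regions in negative libraries it ran from -0.411 to 0.0298, reversed without the thalamus library of mouse 4. Between regions in positive libraries Aldh1l1 was called with only the groups compared (limma adjusted p = 0.00337) and with library weights (0.00464). Il33 was called in the thalamus and in the mean of both regions after rescaling (0.039 and 0.0356), with library weights (0.0345 and 0.0165), without mouse 1 (0.0111 and 0.00387) and without its thalamus negative library (0.0142 and 0.0141), and in the mean also without its spinal cord negative library (0.0137). The cause was not tested. Of 8671 alternative values of 396 named genes past the threshold, 8176 kept direction and call, 495 lost the call and 0 reversed. Of 2327 values of 105 gene lists, 2244 kept both and 83 lost the call. Rescaling moved the median of all features from 0.06 to 0.13 in the thalamus, so small changes there are relative to that shift. Unknown depth limits any statement on genes near 0 FPKM.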

Other observations

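The test of feature classes in this part was chosen only after the result was seen. Other gene groups also moved with the gate. Immediate early and stress genes were lower in positive libraries in 7 of 16 members in each region (7 and 9 adjusted over the list alone), among them Egr1 (-2.12 ± 0.43 in thalamus, -2.72 ± 0.43 in spinal cord) and the chaperone gene Hsp90aa1 (-2.98 ± 0.19 and -1.36 ± 0.19), with adjusted p = 0.071 and 0.072 with an estimated correlation. Axon guidance genes were lower in 8 and 9 of 23 members and higher in 0 and 1 (8 and 10 lower adjusted over the list alone), led by Sema5a (-2.99 ± 0.26 and -4.70 ± 0.26) and Efnb3 (-1.36 ± 0.18 and -4.58 ± 0.18), with adjusted p = 0.019 and 0.0041 with an estimated correlation. Mural cell markers were lower in 4 and 3 of 10 members (5 and 3 adjusted over the list alone; adjusted p = 0.025 and 0.032 with an estimated correlation), with Rgs5 at -3.43 ± 0.29 and -3.01 ± 0.29. Oligodendrocyte and precursor markers were lower in the same libraries as these groups, with medians of -2.54 and -1.05 in the thalamus and -4.29 and -3.65 in the spinal cord.

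Ribosomal protein genes were lower in positive libraries in 15 of 26 members in the thalamus and 9 of 26 in the spinal cord (22 and 11 adjusted over the list alone), with Rpl32 at -1.11 ± 0.18 and -0.91 ± 0.18, but adjusted p was 0.14 and 0.21 with an estimated correlation. Meningeal markers were higher in the spinal cord than the thalamus in 5 of 8 members in positive libraries, also adjusted over the list alone, such as Col1a2 (1.16 ± 0.18), with adjusted p = 0.022 with an estimated correlation.

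Noncoding features were higher in positive libraries. In the thalamus, with features listed at 0 left out, the median log2 fold change was 0.52 for 719 antisense features, 0.52 for 460 lincRNAs, 1.96 for 222 snoRNAs and 2.19 for 143 snRNAs, against -0.08 for 12567 protein-coding genes. In the spinal cord the medians were 0.37, 0.38, 1.21 and 1.498, against -0.02. The features left out were only those at 0 in a library beside 100 FPKM or more in its group. Other values of 0 stayed in and can still affect these medians. At a mean of 10 FPKM or more antisense features still lay 0.61 above protein-coding genes in the thalamus (95% bootstrap interval 0.46 to 0.89). In the spinal cord they lay 0.35 above them (0.19 to 0.68). The intervals are over features and do not measure the spread between mice. Lower detection of weak features in negative libraries is not decided by this. FPKM is scaled by transcript length and depth is unknown, so features at 10 FPKM can still rest on few reads. Reads from overlapping genes, amplification and a difference between the sorted cells may each contribute and were not tested.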
